A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

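Genome Conformation Capture (GCC) joins DNA ends that lie close together in cross-linked nuclei and sequences the joined molecules without enriching for them. Per the labels, Saccharomyces cerevisiae BY4741 was grown at 30 °C and 160 rpm in synthetic complete medium with 2% glucose to an OD600 of 0.6. Cells were fixed with 2% formaldehyde for 10 min, the DNA was cut with MspI for 2 h at 37 °C and joined with T4 DNA ligase for 2 h at 16 °C, and fragments sheared to 200 ± 20 bp were read as 36 bp paired ends. The 2 samples are lane 1 and lane 2 of 1 group, glucose.

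The authors deposited 2 tables of whole-number counts of read pairs per pair of MspI fragments, with the coordinates and the GenBank features of each fragment. Both tables pool the lanes, so lane agreement was not analysed here and there is no replicate error. Every fragment pair was listed in both orders with equal counts, and 1 of each was kept. The first table holds 1449269 read pairs in 358617 fragment pairs. The second holds 3865863 read pairs in 514584 fragment pairs, and contains each pair of the first with an equal or larger count. Of its extra read pairs, 53.1% had both ends in ribosomal DNA and 91.4% had an end in annotated repeats or in the last 20 kb of an arm. Which reads the authors placed in which table is not stated in the labels. From these values the second is treated here as the first plus reads of repeated sequence, and "repeat reads" below rests on that inference. The first table was used throughout, and the second as an alternative. Coordinates are those of the tables, printed counting from 1, on RefSeq chromosomes in which chromosome I has 230208 bp. The build version and the aligner are not given in the sources used here. Gene names and features come from the tables, and symbols of the gene lists were matched through the R64 gene table, which was used for names only. All members of the 12 gene lists were found.

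The unit of analysis was the fragment: 13585 nuclear fragments were listed in either table, with a median length of 571 bp. For joins between nuclear chromosomes, the expected count of a fragment pair was the product of 2 fragment factors, fitted so that each fragment kept its total of interchromosomal read pairs. Windows were 20 kb on each side of a centromere, the last 20 kb of each arm, and 2.5 kb on each side of tRNA genes, replication origins and listed genes. Adjoining fragments with the same kind of feature were counted as 1 locus, which gave 237 tRNA gene loci, 267 origins and 200 loci of Ty elements or long terminal repeats. Observed read pairs between windows of different chromosomes were divided by their expected number. The test was a two-sided permutation test with 100000 circular shifts of the windows along each chromosome, drawn separately per chromosome (10000 for alternatives), so that the smallest p it can give is 2e-05 (0.0002 for alternatives). Benjamini-Hochberg adjustment was made over the 12 gene lists, over the 4 other kinds of locus, and over the 2 relations with length. The threshold was 0.05. Bins of 5 kb had been planned; fragments were used instead, and the bins serve only for display. snoRNA genes, also on the planned list, were not analysed here.

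Intervals of ratios are exact Poisson 95% intervals and intervals of shares are exact (Clopper-Pearson) binomial 95% intervals; PCR copies are not separate molecules, so both cover counting error only. The distance exponent is the slope of log10 read pairs per possible fragment pair on log10 distance from 20 to 300 kb, with an interval from 10000 bootstrap draws of the 16 chromosomes. Correlations with chromosome or arm length used 100000 permutations of the chromosome or arm labels. Single fragment pairs were tested with a one-sided Poisson test, adjusted over all possible interchromosomal pairs. Nuclear joins with mitochondrial and 2-micron DNA were compared with the number expected from each class's share of ends.

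Which comparisons, windows, lists, tests and other settings to use was fixed before the data were examined. The settings fixed then were other windows, each fragment pair counted once, fragment pairs with 2 or more read pairs only, an expectation from fragment numbers alone, annotated repeats and arm ends left out (1062 nuclear fragments), the zone within 50 kb of a centromere left out, positions matched on distance to centromere and end, other distance ranges, chromosome XII left out, a negative binomial test and, for single fragment pairs, the second table. Alternatives chosen after seeing the data were the second table for the other results, both counting once and leaving repeats out, leaving out the 2 chromosomes or arms farthest from the median length, leaving out the highest fragment pair of the ribosomal DNA, and leaving out fragments rich in repeat reads. The last setting drops fragments of which under 80% of the second-table read pairs are also in the first (1509 of 13585 nuclear fragments); a level of 90% was run beside it. The adjustment over 4 kinds of locus and over 2 relations was also added then. So was a rule that an alternative with under 1 expected read pair for a gene list gives no value, which removed 15.

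The text names genes by a rule set in advance: the 10 interchromosomal fragment pairs with most read pairs among those past the threshold, apart from pairs with both ends in repeats, and the 10 highest with both ends in repeats; the 5 highest locus pairs of each kind of locus and of each gene list past the threshold; the 5 highest same-chromosome pairs over 50 kb apart with 10 or more read pairs, of which there was 1; and the chromosomes with the highest and lowest ribosomal DNA ratio.

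The procedure was tested on simulated data with the fitted factors of the 13760 fragments. Without enrichment, p was under 0.05 in 2 of 100 maps for the centromere windows and in 7 of 100 for the tRNA gene windows. With a 2-fold enrichment put into the centromere windows, 10 of 10 maps passed and the mean ratio was 1.79, since the windows' own totals enter the expectation. Of 200 fragment pairs given 5 added read pairs, 200 passed, with 1 other pair. The simulated read pairs were drawn independently, without copies or reads of shared sequence, so this does not give the rate of false calls in the real map. A distance exponent of -1.2 was found as -1.19. For the chromosome length relation over 120 pairs, 5 of 100 simulated sets without a relation had p under 0.05. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.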

Results

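The series maps which parts of the yeast genome lie close together in growing cells. Its title names the positioning of chromosomes and the clustering of functionally related loci as the subject. GCC was applied to 1 group, BY4741 cells growing exponentially in glucose, sequenced in 2 lanes that the tables pool, so nothing was compared between groups and no replicate error could be given. The first table held 1449269 read pairs. Of these, 953433 (65.8%) joined neighbouring nuclear fragments, 236369 (16.3%) joined other fragments of the same nuclear chromosome and 193883 (13.4%) joined different nuclear chromosomes. Pairs of neighbouring fragments can also be DNA left uncut at the site between them, since joined molecules were not enriched. With 3065 of 13585 nuclear fragments under 200 bp, uncut DNA can also reach past a neighbour, and the 2 sources were not separated. The interchromosomal read pairs were spread over 188334 fragment pairs, of which 97.4% had a single read pair, so single contacts were mostly at the limit of counting and the comparisons below rest on sums over windows. Every interval is for counting error unless another source is named.

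The first comparison asked how far each chromosome keeps to itself. Leaving out neighbouring fragments, 45.1% of 430252 nuclear read pairs joined different chromosomes (exact binomial interval 44.9 to 45.2), against 92.6% if ends joined at random. Uncut DNA across short fragments would lower the observed share. Without same-chromosome pairs under 20 kb the share was 80.1%, against 92.5% if ends joined at random. Within the 16 chromosomes, joins at 10 to 20 kb came to 151.5 read pairs per 1000 possible fragment pairs (SD between chromosomes 10.8), 62.4 times the level between chromosomes of 2.43. The level fell to 7.86 times that between chromosomes at 40 to 80 kb and to 1.29 times at 320 to 640 kb. The distance exponent from 20 to 300 kb was -1.23 (bootstrap interval over chromosomes -1.26 to -1.19). The exponent was -1.47 from 5 to 100 kb and -0.867 from 50 to 500 kb, and the share between chromosomes ranged from 6.81% (fragment pairs with 2 or more read pairs) to 80.1% (same-chromosome pairs under 20 kb left out).

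**Figure D1:**
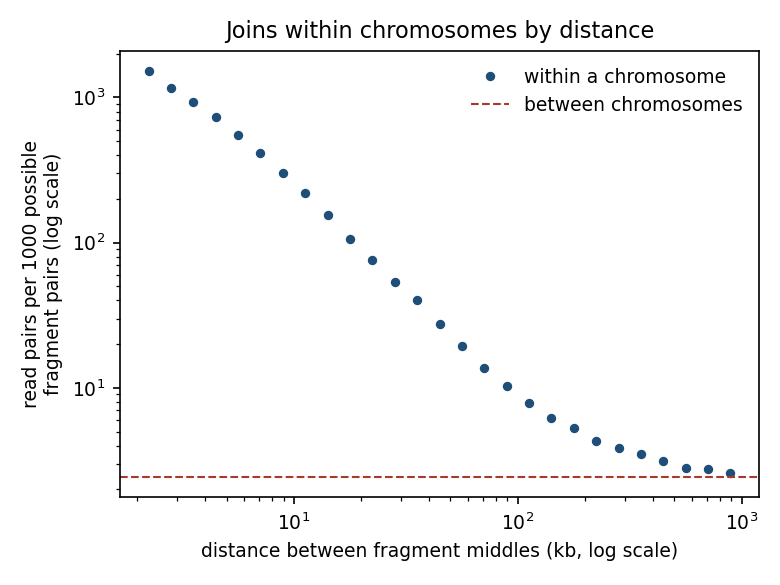
Read pairs per 1000 possible fragment pairs (log scale) against the distance between fragment middles in kb (log scale), for all nuclear chromosomes together; the dashed line is the level between chromosomes, 2.43. The points fall with distance and approach the dashed line beyond 320 kb.

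Centromeres, the sites at which spindle microtubules attach, were joined to each other across chromosomes more often than expected. Windows of 20 kb on each side of the 16 centromeres shared 1825 read pairs against 645 expected, a ratio of 2.83 (2.70 to 2.96), and shifted windows gave 0.916 to 1.12 (permutation p = 2e-05, the smallest possible; adjusted over 4 kinds of locus 4e-05). Each of the 16 centromeres was above expectation, from 2.42 for CEN14 to 3.25 for CEN1. All 120 centromere pairs had a ratio above 1, with a median of 2.85, and the intervals of 104 lay above 1. The pairs with most read pairs were CEN9 with CEN11 (30 read pairs, ratio 3.68), CEN5 with CEN12 (28, ratio 5.35), CEN4 with CEN11 (28, ratio 3.68), CEN9 with CEN16 (24, ratio 3.70) and CEN7 with CEN10 (23, ratio 3.36). The ratio fell with distance from the centromere, from 4.10 (3.46 to 4.82) within 5 kb to 1.58 at 20 to 40 kb and 1.12 at 80 to 100 kb. Leaving out 1 chromosome at a time gave 2.79 to 2.88. In the second table, with the repeat reads, the ratio was 1.96 and not past the threshold (permutation p = 0.166).

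**Figure D2:**
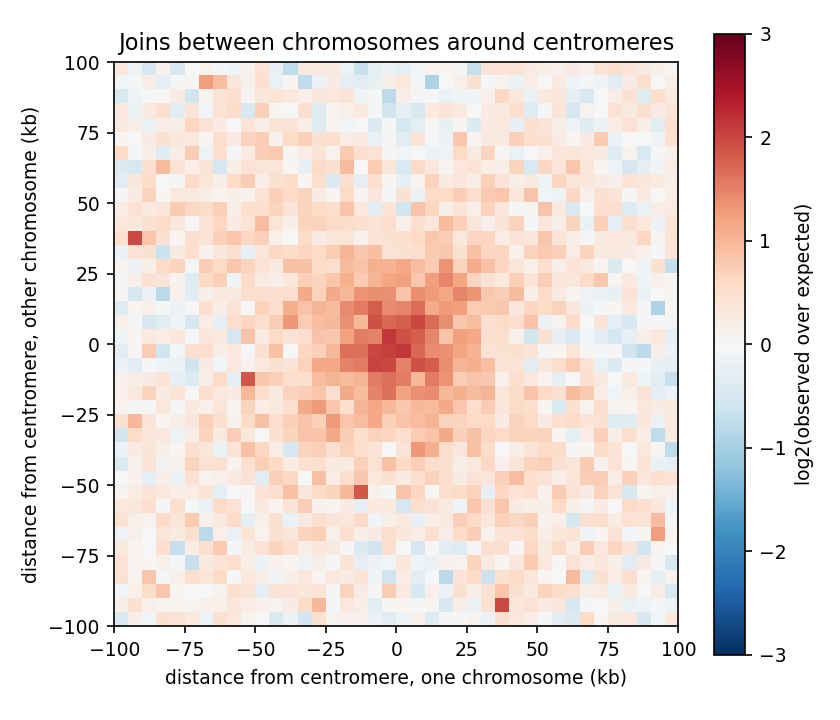
Log2 of observed over expected read pairs in bins of 5 kb, by distance from the centromere of each of the 2 joined chromosomes (kb), summed over all pairs of the 16 chromosomes. Values are raised where both distances are near 0, and 2 single bins away from there are about as high, at the positions of the pairs YARWDELTA7 with YGLWDELTA8 and SSA1 with SSA2 (each drawn on both sides of the diagonal).

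Chromosome ends, which carry the telomeres and gene families such as the seripauperin (PAU) genes, were also joined across chromosomes above expectation. The last 20 kb of the arms shared 544 read pairs against 133 expected, a ratio of 4.08 (3.75 to 4.44; shifted zones 0.916 to 1.12; permutation p = 2e-05, the smallest possible; adjusted 4e-05). The ratio was 54.2 (46.1 to 63.3) in the last 5 kb, 10.3 (7.69 to 13.4) at 5 to 10 kb, 1.57 (1.26 to 1.93) at 10 to 20 kb, 1.39 (1.19 to 1.61) at 20 to 30 kb and 0.990 (0.831 to 1.17) at 30 to 40 kb. The arm pairs with most read pairs were the right arms of II and VII (23), the left arm of VII with the right arm of IX (20), the left arm of III with the right arm of XI (17), and, with 14 each, the left arm of I with the right arm of IV and the left arms of II and XI. Most of this excess lay in fragments rich in repeat reads: without them, 395 of 638 fragments of the zone were lost and the ratio was 1.54 (1.23 to 1.90; permutation p = 0.0002, the smallest possible for an alternative). The second table gave 2.79 (permutation p = 0.0754), and the last 40 kb gave 1.49. The ratio was 19.7 in the last 10 kb, 11.6 with fragment pairs of 2 or more read pairs and 2.29 with the expectation from fragment numbers, each past the threshold.

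**Figure D3:**
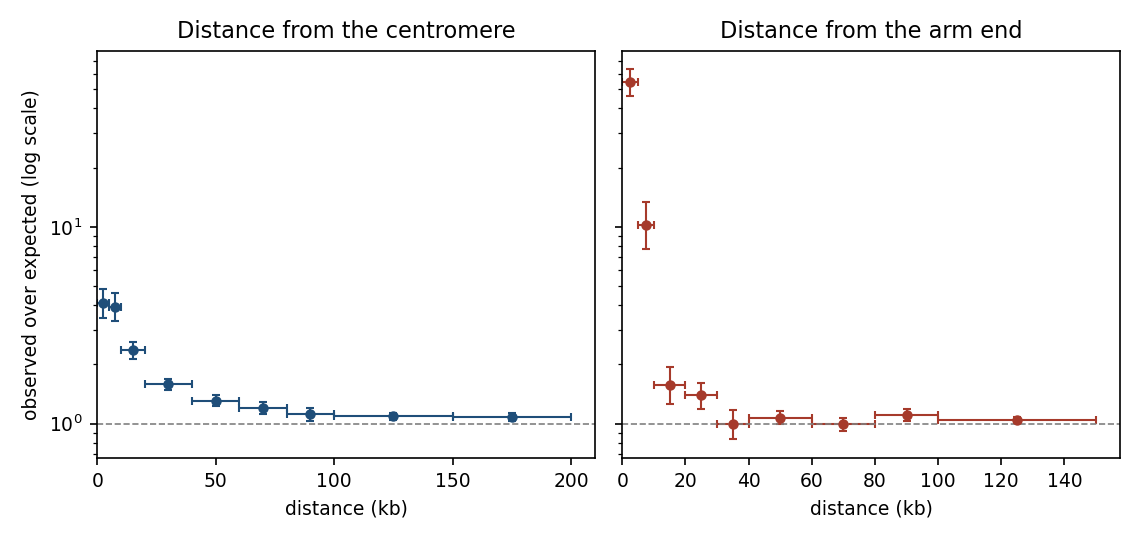
Observed over expected read pairs between chromosomes (log scale) when both fragments lie at the stated distance in kb from their centromere (left) or from the end of their arm (right); horizontal bars span each distance class and vertical bars are 95% counting intervals. The ratio is 4.10 within 5 kb of the centromeres and 54.2 within 5 kb of the ends, and the dashed line marks 1.

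Short chromosomes were compared with long ones, and arms of like length with arms of unlike length. Among the 120 chromosome pairs the highest ratios were those of I with VI (1.33), III with VI (1.32), I with III (1.28), III with IX (1.21) and I with IX (1.20), all pairs of short chromosomes, and the lowest was I with XV (0.851). The intervals of 12 pairs lay above 1 and those of 13 below. Over all pairs, the ratio went with the product of the lengths at Spearman's rho = -0.119 (permutation p = 0.0567; adjusted over 2 relations 0.113) and Pearson's r = -0.185 (p = 0.0702; adjusted 0.140), not past the threshold. Without I and IV, the chromosomes farthest from the median length, rho was -0.0158 (p = 0.782) and r was -0.157 (p = 0.0808). Without the zone near centromeres, annotated repeats, chromosome XII or fragments rich in repeat reads, in turn, p of rho lay between 0.0364 and 0.0487, just past the threshold before adjustment. In the second table rho was 0.334 (permutation p = 0.000730) and r was -0.0263 (permutation p = 0.621). For the 480 pairs of arm ends, the ratio did not follow the difference in arm length (rho = -0.0337, permutation p = 0.582; r = 0.0141, p = 0.756; adjusted p the same; without the 2 arms farthest from the median, rho = -0.100, p = 0.0789, and r = -0.0402, p = 0.438). With the last 40 kb of each arm, rho was -0.150 (p = 0.00168) and r was -0.0689 (p = 0.152). In the zone from 20 to 40 kb, rho was -0.106 (p = 0.0238) and r was -0.0788 (p = 0.0677).

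Genes for transfer RNA, which are transcribed by RNA polymerase III, were tested as a class of functionally related loci. The 237 tRNA gene loci shared 1247 read pairs against 1178 expected, a ratio of 1.06 (1.00 to 1.12; permutation p = 0.0398), which did not pass after adjustment over the 4 kinds of locus (0.0530). The highest pairs lay between tRNA gene fragments at 197139 to 197825 of chromosome II, beside a sigma and a delta element, and at 179265 to 181314 of chromosome VI: 4 overlapping window pairs there shared 15 read pairs each. The next was IV (437384 to 437882) with XVI (571471 to 572313), with 4 read pairs. Without the fragments rich in repeat reads, which included 227 of the 278 fragments with a tRNA gene, the ratio was 1.01 (permutation p = 0.725), and without the zone within 50 kb of centromeres it was 1.02 (permutation p = 0.489). The tRNA gene ratio passed the unadjusted threshold with windows of 0.5 times the size (1.24, permutation p = 0.00180) and of 2 times the size (1.03, permutation p = 0.0166), with fragment pairs of 2 or more read pairs (1.64, permutation p = 0.0148) and in the second table (2.74, permutation p = 0.00200). Replication origins, the sites where DNA synthesis starts, gave 2560 read pairs against 2513 expected over 267 loci, a ratio of 1.02 (0.980 to 1.06; permutation p = 0.402). The 5 origin pairs with most read pairs all involved ARS1200-1, the origin of the ribosomal DNA. It was joined with ARS607 (13 read pairs against 2.45 expected), ARS1623 (13 against 6.88) and ARS719 (13 against 8.67). ARS1528 had 10 against 5.27 and ARS1633 had 8 against 2.70. The intervals of the ratios with ARS719 and ARS1528 include 1, and that with ARS1623 starts at 1.01. With an expectation from fragment numbers alone the origin ratio was 1.29 (permutation p = 0.0150). Under that expectation ribosomal DNA had 64.8 times the expected read pairs with the other chromosomes together, so ARS1200-1 may raise the origin ratio. This was not tested. Ty retrotransposons and their long terminal repeats, reported apart as repeated sequence, gave 1.12 (1.04 to 1.21; permutation p = 0.000460), which fell to 0.969 (p = 0.274) without the fragments rich in repeat reads. Their highest pairs were YARWDELTA7 on I with the YGLWDELTA8 region on VII (58 read pairs) and YARCDELTA8 on I with YHRCDELTA14 beside FLO5 on VIII (7).

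Of 12 gene lists, the genes of 1 were joined across chromosomes beyond the threshold. The 14 heat shock genes shared 69 read pairs against 6.48 expected, a ratio of 10.6 (8.28 to 13.5; permutation p = 0.000240, adjusted 0.00288). Of these, 67 joined SSA1 (I, fragment 138158 to 143379) with SSA2 (XII, fragment 94997 to 98720), which encode closely related Hsp70 chaperones of the cytosol, 1 joined the Hsp90 genes HSC82 and HSP82, and 1 joined SIS1, the gene of a J-protein co-chaperone, with SSA2. With each fragment pair counted once the ratio was 0.533, so the call of the list rests on the SSA1 and SSA2 fragments alone. With positions matched on distance to centromere and end, adjusted p was 0.206. Genes of glycolysis and fermentation had a ratio of 1.54 (1.10 to 2.11; permutation, adjusted p = 0.470), with 39 read pairs against 25.3 expected. The 137 ribosomal protein genes had 0.979 (0.899 to 1.06) with 555 read pairs, the 34 proteasome genes 1.06 (0.776 to 1.41), the citric acid cycle genes 1.19 (0.692 to 1.90), the histone genes 1.85 (0.503 to 4.72) and the hexose transporter genes 1.28 (0.415 to 2.98). Ratios below 1 were found for the genes of the nuclear pore (0.647, 0.237 to 1.41), of phosphate uptake and its control (0.758, 0.0919 to 2.74), of methionine and sulfur (0.736, 0.337 to 1.40) and of ribosome biogenesis (0.736, 0.337 to 1.40). The 7 galactose genes shared 0 read pairs against 1.99 expected, which allows a ratio of up to 1.86. Adjusted p of these lists lay between 0.470 and 0.880. The intervals of the histone and hexose transporter lists reach past the ratio of the centromeres, so clustering of that size was not excluded for them at this depth. Those of the other lists that did not pass end below it, but this alone does not exclude such clustering. The intervals cover counting error only, and shifted windows of the galactose list ranged from 0 to 3.99. With windows of 0.5 times the size, several of these intervals passed the centromere ratio, as for ribosome biogenesis (up to 4.28). Those of ribosomal protein genes (1.27), the proteasome (2.08) and the nuclear pore (2.12) did not. The centromere ratio is also for wider windows, 20 kb against 2.5 kb.

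**Figure D4:**
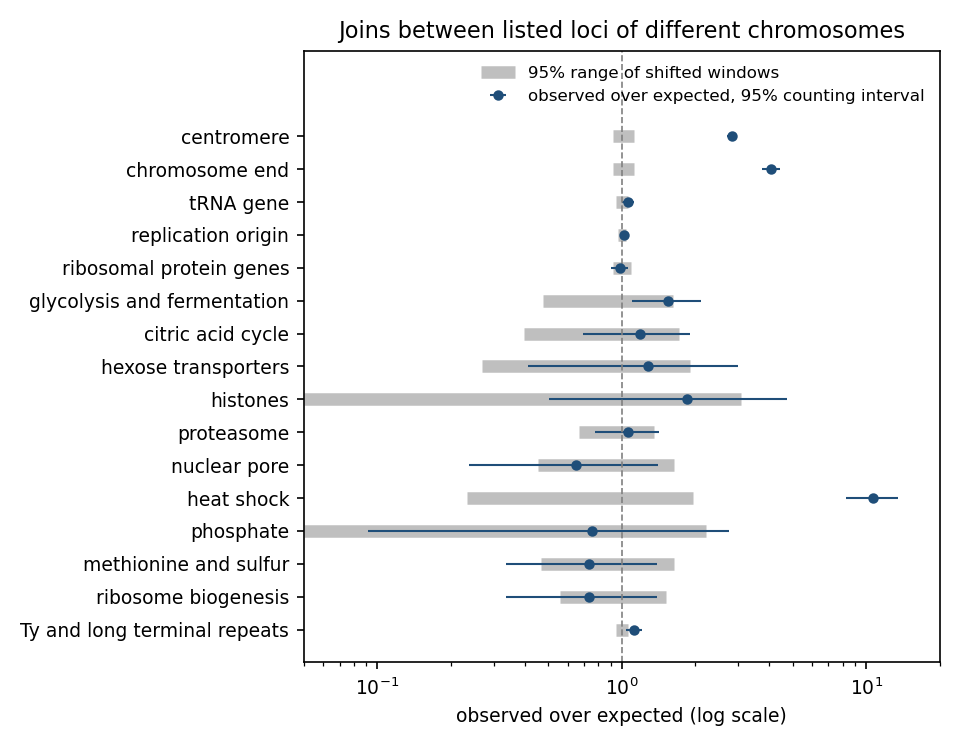
Observed over expected read pairs between listed loci of different chromosomes (log scale), for 4 kinds of locus, 11 of the 12 gene lists and Ty elements with long terminal repeats; points are the ratios with 95% counting intervals and grey bars the 95% range of shifted windows. Centromeres (2.83), chromosome ends (4.08) and the heat shock list (10.6) lie far outside their grey bars; the galactose list, with 0 read pairs, is not drawn.

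The ribosomal DNA on chromosome XII (451474 to 469370), which forms the nucleolus, shared 5652 read pairs with the other 15 chromosomes. Chromosome VII had the highest ratio, 682 read pairs against 565 expected (1.21, 1.12 to 1.30), and chromosome I the lowest, 86 against 110 (0.779, 0.623 to 0.962). The ratios differed between chromosomes beyond counting error (chi-square p = 0.000206). Of the 682 read pairs, 115 belonged to a single fragment pair at ROM1, and without it the ratio of VII was 1.00 (0.923 to 1.09). The 15 chromosomes then did not differ past the threshold (chi-square p = 0.283). Ribosomal DNA was joined with the centromere windows at 0.899 (0.800 to 1.01) and with the last 20 kb of the arms at 0.906 (0.763 to 1.07) of the expected number.

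Mitochondrial DNA, which lies outside the nucleus, served as a measure of chance joining. Nuclear and mitochondrial fragments shared 19866 read pairs, 0.822 (0.811 to 0.834) of the number expected from their shares of ends. Different nuclear chromosomes were joined at 0.496 (0.494 to 0.498) of that number, and nuclear DNA with the 2-micron plasmid, a multicopy circle kept in the nucleus, at 0.541 (0.532 to 0.550). By chromosome, with the expected numbers scaled to the total of nuclear joins with mitochondrial DNA, the ratio ran from 0.927 for VIII to 1.13 for XII. The shares of ends behind 0.822, 0.496 and 0.541 include ends of joins within a chromosome. Nuclear DNA had 236369 such read pairs between fragments that are not neighbours, against 2548 within mitochondrial DNA. The level between nuclear chromosomes was below that with mitochondrial DNA in the first table. Such ends lower it, so it cannot be read as below chance joining. In the second table the order was turned around, with 0.578 (0.577 to 0.579) between nuclear chromosomes and 0.482 (0.477 to 0.488) with mitochondrial DNA. With each fragment pair counted once, the ratio was 0.652 between nuclear chromosomes, 0.947 with mitochondrial DNA and 1.01 (0.993 to 1.03) with the 2-micron plasmid, whose ratio in the second table was 0.194.

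Single fragment pairs far above chance were sought among 7.99e+07 possible interchromosomal pairs. The test passed 135, of which 37 had both ends in annotated repeats or arm ends. The lowest count among the 135 was 2 read pairs. Among the other 98, the highest joined YGR068C and ROM1 (VII, 625454 to 627907), with ribosomal DNA (XII, 459298 to 460025), with 115 read pairs against 0.651 expected. SSA1 with SSA2 had 67, YIL169C (IX, 22005 to 23966) with HPF1 (XV, 27758 to 29396), which encodes a cell wall mannoprotein, 36, and the pyruvate carboxylase genes PYC2 (II, 660171 to 660641) and PYC1 (VII, 386797 to 388383) 21. RPA190, the gene of the largest subunit of RNA polymerase I (XV, 963856 to 964030), was joined with the SAM3 and SAM4 fragment (XVI, 24448 to 27746) in 12 read pairs, and the tRNA genes on II and VI named above in 10. The rest joined ribosomal DNA fragments with the ammonium permease gene MEP2 and its neighbours AAH1 and RLR1 on XIV (20), with TUB2 and RPO41 on VI (14), with the gene of the telomere-binding protein Rap1 and YNL217W on XIV (11) and with ADA2 and UTP6 on IV (9). For SSA1 with SSA2 the second table held 1706 read pairs, for YIL169C with HPF1 1453 and for PYC2 with PYC1 186. Ribosomal DNA had 193 there with MEP2, 110 with ADA2 and 20 with TUB2, and the tRNA genes on II and VI had 68. The counts of ROM1 (115) and RAP1 (11) with ribosomal DNA and of RPA190 with SAM3 and SAM4 (12) were the same in both tables. A negative binomial test, which allows for more spread than counting error, passed 22 pairs. Of these, 15 had both ends in repeats and 7 did not, so most of the 98 did not pass it. A constant mean passed 4830, so the number depends on the model.

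Pairs with both ends in repeats are uncertain, since their reads can belong to more than 1 place. The highest were YARWDELTA7 on I with the fragment of MST27 and YGLWDELTA8 on VII (58 read pairs, 456 in the second table), the PAU11 and YPS5 fragment on VII with that of YPS6 and PAU15 on IX (20, 1445 in the second table), a fragment on II (809697 to 809824) with PAU12 on VII (16) and TEL02L with TEL11L and PAU16 (14). PAU8 on I with PAU10 on IV had 13, as did TEL08L with TEL11R. The maltose permease family members MPH2 on IV and MPH3 on X had 12 (1188 in the second table), as did TEL07L with TEL10R. TEL03L with PAU19 and TEL13R had 10, and TEL08L with TEL11L had 9. Of these 37 pairs, 36 had more read pairs in the second table. Within chromosomes, 1 pair over 50 kb apart had 10 or more read pairs and an excess over the distance expectation to be named: FLO9 (I, 24168 to 25496) with FLO1 (I, 206177 to 206446), related flocculin genes near opposite ends of the chromosome, with 12 read pairs and 20 in the second table.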

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

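The tests of arm ends without fragments rich in repeat reads and of flanks without called pairs, with their division by table and by ribosomal DNA, were chosen only after the results were seen, and the other tests here before. Outside the comparisons above, the first table held 16 read pairs within the cloning vector pUC19, a signal in data that no comparison used, and 0 between pUC19 and nuclear DNA.

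Centromere windows of different chromosomes shared 2.83 times the expected number of read pairs. Read pairs piled up on a few fragment pairs of repeated sequence would have lost the excess when each fragment pair was counted once and repeats and arm ends were left out, but the ratio stayed at 2.83, against 0.911 to 1.11 for shifted windows. Joins of these windows with mitochondrial DNA were 1.13 times (1.06 to 1.20) those of other nuclear fragments. This was below the level set in advance for more DNA ends from these windows in chance joining. The value adds little, since each fragment's total already enters the expectation, so more ends alone would not raise the ratio. Piling up is argued against, and the reads of the second table, where the ratio was 1.96 and the shifted windows gave 0.284 to 3.23, leave open how repeat reads would enter. With 1 group, no biological explanation was tested against another condition; that centromeres lie close together in these nuclei is a hypothesis that these values may fit.

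Arm ends of different chromosomes shared 4.08 times the expected number of read pairs. Piling up on a few fragment pairs is argued against as the whole cause, since counting each fragment pair once left 2.85 (shifted zones 0.918 to 1.11). That ratio was lower than 4.08, with 344 read pairs counted in place of 544, so piling up may have given part of the excess. Reads of sequence shared between ends may account for most of the excess: the zone from 20 to 40 kb, at 1.11 (1.02 to 1.21), lay just inside the range of shifted zones (0.919 to 1.11, the second bound within rounding of the value), and leaving out fragments rich in repeat reads took the ratio from 4.08 to 1.54. Shared sequence in the fragments left out is argued against as the whole cause, since 1.54 (1.23 to 1.90) still lay above the shifted zones (0.913 to 1.11). The stricter level gave 1.63. Fragments kept can still hold some repeat reads, and fragment pairs were not counted once in this setting. Shared sequence together with piling up was therefore not tested as the whole cause. How much of the excess in the last 10 kb came from contacts stays open, and no biological explanation was tested.

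Of the fragment pairs above chance in the Poisson test, 98 did not have both ends in repeats, 16 of them with 1 end there. Only 7 pairs without both ends in repeats passed the negative binomial test. The 98 could come from reads of sequence shared between 2 places, from copies of single joined molecules, or from contacts. Flanking fragments within 5 kb were joined at 1.71 (1.45 to 2.01) of expectation, and still at 1.33 (1.09 to 1.59) without called pairs that adjoin each other. Leaving out called pairs took the observed flank read pairs from 147 to 114, with 85.9 expected both times. Called pairs are picked for their high counts, so this step lowers the ratio by itself. The flank ratios of the 10 and the 88 pairs below also leave them out. An interval above 1 had been set in advance as the outcome against shared sequence. The test cannot decide this, since the 37 pairs with both ends in repeats also had raised flanks (16.6, 11.9 to 22.6). Of the 98, 88 gained no reads in the second table, whereas 36 of the 37 pairs with both ends in repeats did. The 10 pairs that gained reads had flanks at 1.63 (1.19 to 2.17), with 1.43 (0.995 to 1.99) for the 3 with ribosomal DNA and 2.90 (1.45 to 5.19) for the other 7, among which the tRNA genes on II and VI had 6 flanking read pairs against 1.37 expected, YIL169C with HPF1 3 against 0.586, PYC2 with PYC1 1 against 0.520 and SSA1 with SSA2 0 against 0.494, so that single pairs are not decided. For the 88 the flanks came to 1.18, with an interval that includes 1. This cannot decide on copies of single joined molecules, since leaving out called pairs favours a ratio near 1 and the interval also allows an excess. The flanks of ROM1 with ribosomal DNA showed no excess (2 read pairs against 5.36 expected). Copies and shared sequence therefore both stay open, and no biological explanation was tested.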

How the results depend on the processing

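The second table for results other than single fragment pairs, fragments rich in repeat reads left out at either level, repeats left out together with counting once, the 2 chromosomes or arms farthest from the median length left out, the highest fragment pair left out and all alternatives of the Ty elements were chosen after seeing the data; the others were planned. No paired analysis was possible because there is 1 group, and the alternatives without replicate 1 and without replicate 2 were not run, since the tables pool the lanes. Of 200 alternatives, 126 kept their direction and their side of the threshold or their range. The ratio of centromeres and that of arm ends passed in every alternative except the second table. For arm ends, the setting with repeats left out dropped only fragments with ribosomal RNA, Ty elements or long terminal repeats. It kept the telomere fragments and the arm ends, and gave 3.44. For all values below the cause was not tested, except that the SSA1 and SSA2 pair accounts for the heat shock list. Depth limits the gene lists: 15 alternatives with under 1 expected read pair gave no value.

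In the second table, the ratio was 1.96 for centromeres and 2.79 for arm ends, both no longer past the threshold, while tRNA genes (2.74, permutation p = 0.00200) and Ty elements (2.42, permutation p = 0.00780) passed. There rho with chromosome length was 0.334 and rho with arm length 0.00543, both turned in sign, the share between chromosomes was 38.4%, the ribosomal DNA ratio of VII was 1.00 and the mitochondrial ratio 0.482. The 7 gene lists that passed there were histones (289.7), phosphate (161.8), glycolysis and fermentation (68.5), heat shock (67.9), hexose transporters (45.7), citric acid cycle (28.7) and ribosomal protein genes (13.0), of which phosphate and ribosomal protein genes turned in direction. Nuclear pore (4.55), methionine and sulfur (1.42) and ribosome biogenesis (1.91) turned without passing, and 11905 fragment pairs passed in place of 135.

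With each fragment pair counted once, the tRNA gene ratio was 1.04 (permutation p = 0.0944), the heat shock ratio 0.533, the share between chromosomes 60.2%, the ribosomal DNA ratio of VII 1.04 and the mitochondrial ratio 0.947, and 0 gene lists passed. With fragment pairs of 2 or more read pairs, the share between chromosomes was 6.81%, the ratio of ribosomal protein genes 1.62, and those of glycolysis and fermentation and of the proteasome 0. With the expectation from fragment numbers, the ratio was 1.08 for tRNA genes (permutation p = 0.152) and 1.29 for origins (now past the threshold, p = 0.0150). It was 1.02 for ribosomal protein genes, 0.961 for hexose transporters, 0.980 for Ty elements and 79.0 for ribosomal DNA with VII. For ribosomal DNA with all other chromosomes together it was 64.8 (5652 read pairs against 87.2 expected), so a high ratio was not particular to VII. The origins include that of the ribosomal DNA, and their ratio without it was not computed.

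With repeats left out, the tRNA gene ratio was 1.03 (p = 0.294), the heat shock ratio 0.370, rho with chromosome length -0.126 (p = 0.0470), 0 gene lists passed, and 77 fragment pairs did. With fragments rich in repeat reads left out, the tRNA gene ratio was 1.01 (1.00 at the stricter level), the heat shock ratio 0, the hexose transporter ratio 0.897, the Ty ratio 0.969, rho with chromosome length -0.121 (p = 0.0487), 0 gene lists passed, and 62 fragment pairs did, all among the 135. Arm ends, at 1.54 and 1.63 at the 2 levels, stayed past the threshold, as did centromeres at 2.85 and 2.84. Without the zone near centromeres, the ratio was 1.02 for tRNA genes (p = 0.489), 0.354 for heat shock and 0.989 for the proteasome, 0 gene lists passed, and rho with chromosome length was -0.154 (p = 0.0373). With matched positions, the tRNA gene ratio of 1.06 had permutation p = 0.107, and 0 gene lists passed.

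Windows of the smaller size gave 0.995 for origins, 1.07 for ribosomal protein genes and 1.83 for ribosome biogenesis. Windows of the larger size gave 1.02 for ribosomal protein genes, 0.970 for the citric acid cycle, 0.908 for histones and 1.55 for phosphate. With all pairs kept the share between chromosomes was 14.01%, and without same-chromosome pairs under 20 kb 80.1%. The distance exponent was -1.47 from 5 to 100 kb and -0.867 from 50 to 500 kb. Without chromosome XII, rho with chromosome length was -0.134 (p = 0.0364). For arm length, Spearman's correlation was -0.150 for the last 40 kb and -0.106 from 20 to 40 kb. Without the highest fragment pair the ribosomal DNA ratio of VII was 1.00. A constant mean passed 4830 fragment pairs and a negative binomial test 22.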

Other observations

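The tests in this part were set before their results were seen. Loci at like distances from their centromeres were compared across chromosomes. Among 18 arms, loci 50 to 300 kb from their centromeres that differed by under 25 kb in that distance were joined at 1.11 (1.08 to 1.14) of expectation, above the 1.01 to 1.06 of arms shifted along that range (one-sided permutation p = 0.001, the smallest possible with 1000 shifts). Arms that lie side by side may give this, but joins were still raised near centromeres in that range (1.31 at 40 to 60 kb and 1.20 at 60 to 80 kb), and no test separated the 2. On chromosome XII, pairs 50 to 300 kb apart that span the ribosomal DNA were joined at 0.373 (0.302 to 0.457) of the distance expectation, below the 0.721 to 1.24 of random nuclear points, so the array may keep its flanks apart. The reference sequence holds only part of the repeat array, so distances across it are longer in cells than in the coordinates. The 2-micron plasmid was not found nearer to arm ends: its ratio to mitochondrial joins there was 1.09 (0.945 to 1.25) times that elsewhere, and in centromere windows it was 0.789 (0.712 to 0.874). The left and right ends of the same chromosome were joined at 3.20 (1.75 to 5.37) times the number that the same fragment factors give for ends of different chromosomes, with 14 read pairs, an interval that overlaps that of ends of different chromosomes, 4.08 (3.75 to 4.44).

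The silent mating cassettes HML and HMR on chromosome III shared 0 read pairs in the first table and 568 in the second, HML and MAT shared 0 and 1601, and MAT and HMR shared 1 and 585; these loci hold copies of the same sequence. URA3, LEU2 and MET17 are deleted in BY4741. No listed fragment was annotated with URA3. LEU2, a leucine synthesis gene, had a fragment (III, 91133 to 91574) with 1 read pair to its neighbours, against a median of 143 per nuclear fragment, and another (III, 91575 to 93297) with 91. The MET17 fragments on either side of XII 732578 to 733107 had 88 and 112, and no fragment between these positions was listed. Fragments of HIS3, another marker gene of this strain, had 209 and 218, which does not show that the gene is whole.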
